A study of Mus musculus with 3 samples.

How the data were processed

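Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where HA-tagged NUR77, an orphan nuclear receptor encoded by Nr4a1, sat on the genome of C2C12 cells, a mouse myoblast line that can be grown as proliferating muscle precursors. Per the labels' protocols, a stable line carried an HA-NUR77 construct inducible by doxycycline, and 18 dishes of 15 cm were used per replicate. Doxycycline at 1 µg/mL was added 24 h after seeding and left for 18 h. Proteins were crosslinked with 2 mM disuccinimidyl glutarate for 45 min and then with 1% formaldehyde for 15 min, chromatin was sheared to about 200 bp, and 2 µg of anti-HA antibody was used per immunoprecipitation. The labels name different antibody suppliers in different fields. The series has 3 samples in 1 group, numbered 1 to 3 in the labels. An uninduced culture, an input library or a control antibody was not analysed here, so positions were compared between replicates and against random placements, not against a control. The labels do not say whether the 3 replicates came from separate days, so the spread between them may be partly technical. The series title speaks of macrophages, whereas all samples analysed here are C2C12.

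Each replicate came with its own deposited peak list: chromosome, start, end, a peak name and a score. Per the file contents, the peak names carry the name of the caller MACS, and the genome build is mm9 per the submitters' processing notes. The caller version, its settings and the control it was given are not given in the sources used here. The deposited score of each peak was used in the tests only to rank or filter peaks within its own list, because which statistic it is was not stated. Scores printed for several replicates are quoted as deposited and may not be on the same scale. The lowest score was 70.02 in replicate 1 and 70.01 in replicates 2 and 3. The peak numbers in the names have gaps (160 of 4628 numbers in replicate 1, 289 of 8045 in replicate 2 and 490 of 11307 in replicate 3). Peaks may thus have been left out after calling, which was not tested. Between 97.96% and 98.68% of the peak widths in a list were exact multiples of 50 bp, so a boundary is resolved to about 50 bp. A further deposited file holds 13891 intervals merged over the replicates, with coordinates and no score or other value. The number of reads behind each list is unknown, and no count of reads per peak was used.

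The lists were compared with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 in Python 3.11.15, and the main overlap counts were checked with bedtools 2.31.1, which gave identical numbers. A peak was called shared when it overlapped a peak of another list by at least 1 bp. Overlapping or abutting peaks of the 3 lists were joined into regions, and regions with a peak from at least 2 replicates were used for position and spacing. The background was 1000 circular shifts of a list, with a random offset on each chromosome inside the span from its first to its last peak; these keep the number, width and local clustering of peaks. Such p-values are one-sided, and 0.001 is the smallest that 1000 shifts can give. Spacing was compared with 1000 uniform placements inside the same spans. Chromosome density was tested by drawing as many 5 Mb bins at random from the whole genome as a chromosome has, 100000 times, two-sided, with Benjamini-Hochberg adjustment over 20 chromosomes; 1e-05 is the smallest p these draws can give. Intervals on shares are 95% Wilson intervals and cover counting error over peaks only. Simulated lists had the sizes of replicates 1 and 3 and 0%, 50% or 90% planted sharing. Of 4468 peaks, 0.27%, 49.2% and 89.3% were recovered as shared. Among 40 repeats without sharing, 0 reached a permutation p of 0.05. Planted peaks always overlapped their partners, and all simulated lists were placed uniformly. The simulations thus check the counting, not how the shifts behave on clustered peaks.

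The overlap rule, the list length, the score threshold, the random background, the set of regions, the near distance and each replicate were varied. These choices, the gene lists, the motifs and the rule for naming regions were fixed before the data were examined, except the removal of dense windows, the score threshold for chromosome density and the test of chromosome density in regions with all 3 replicates, which were added later. For chromosome density the plan named only the mean and SD over the lists, not the permutation test of bins. The rule for naming regions gave the 15 regions present in all 3 replicates with the highest mean within-list score rank, and the densest 100 kb window. A sequence or annotation of mm9 was not used here, and the gene table at hand is for another assembly (GRCm38), so no peak was assigned to a gene, exon, intron or promoter. The planned tests of promoter position, of gene lists (among them oxidative phosphorylation, mitochondrial biogenesis, glycolysis, myogenic and macrophage genes), and of NUR77 and YY1 motifs were therefore not run. All positions are 1-based mm9 coordinates.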

Results

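Genome-wide binding sites of doxycycline-induced HA-NUR77 were profiled by anti-HA ChIP-seq in 3 replicates of C2C12 myoblasts. The deposited lists held 4468 peaks for replicate 1, 7756 for replicate 2 and 10817 for replicate 3, a mean of 7680 ± 3175 (SD, n = 3). Replicate 3 thus had 2.42 times as many peaks as replicate 1. Peaks were narrow in all lists, with a median width of 300 bp in replicates 1 and 2 and 336 bp in replicate 3. Together they covered 1.38 Mb, 2.41 Mb and 3.57 Mb of the genome in replicates 1, 2 and 3. The median caller score, as deposited by the authors, was 114.84, 121.12 and 125.74 in the same order, and the highest scores were 1850.5, 1796.3 and 1880.0. All peaks in the 3 replicate lists lay on chromosomes 1 to 19 and X. Sequencing depth was not given, so whether the lists differ in length because of depth cannot be read from the lists.

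The first question was whether the replicates marked the same sites. The shorter list was largely contained in the longer ones. Of the replicate 1 peaks, 90.4% (95% interval 89.5 to 91.2%) overlapped a replicate 3 peak and 84.1% (83.0 to 85.1%) overlapped a replicate 2 peak. Of the replicate 2 peaks, 80.5% (79.6 to 81.4%) were found in replicate 3. In the opposite direction the shares were lower, with 37.3% of replicate 3 peaks found in replicate 1, 57.7% of them in replicate 2, and 48.4% of replicate 2 peaks in replicate 1. Circular shifts gave means between 0.12% and 0.30% for the 6 shares, and at most 0.58% in any shift. Each observed share exceeded all 1000 shifts (one-sided permutation p = 0.001). With the lists cut to their 4468 best-scoring peaks, the overlap was 69.2% for replicates 1 and 2, 68.6% for replicates 1 and 3, and 73.3% for replicates 2 and 3.

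Joining the 3 lists gave 12580 regions. A peak from all 3 replicates was present in 3591 of them (28.5%), and 6865 (54.6%) had a peak from at least 2. Shifted lists gave on average 45.7 regions with at least 2 replicates and at most 2 regions with all 3 (one-sided permutation p = 0.001 for both counts). Of the regions with exactly 2 replicates, 2653 had peaks from replicates 2 and 3, 449 from replicates 1 and 3, and 172 from replicates 1 and 2. Regions seen in a single replicate numbered 256 for replicate 1, 1339 for replicate 2 and 4120 for replicate 3. Before joining, the peaks of regions with all 3 replicates had a median width of 300, 350 and 400 bp in replicates 1, 2 and 3, compared with 250 bp in each list for peaks of regions from a single replicate.

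**Figure D1:**
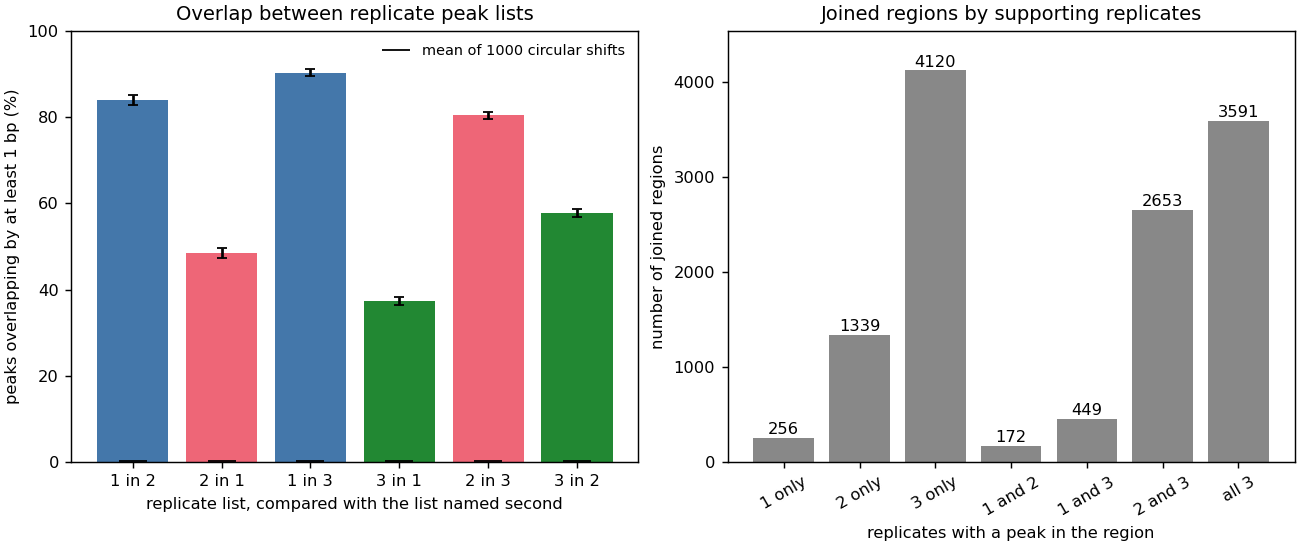
Left, percent of the peaks of one replicate list that overlap the list named second by at least 1 bp (bars, with 95% Wilson intervals) and the mean of 1000 circular shifts (black dashes, all below 0.30%). Right, number of joined regions by the replicates that have a peak there; 3591 regions carry all 3 and 4120 carry replicate 3 alone.

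The sites found in more replicates were those with higher caller scores. Peaks in regions with all 3 replicates had a median within-list score percentile of 71.6 ± 11.9 (SD, n = 3 lists), those in 2 replicates 36.9 ± 13.1, and those in a single replicate 21.8 ± 4.1. The order was the same in each of the 3 lists, with medians of 18.1, 23.6 and 58.4 in replicate 1 and 26.3, 49.9 and 81.6 in replicate 3. Peaks of regions with all 3 replicates made up 80.4%, 46.3% and 33.2% of the lists of replicates 1, 2 and 3. The percentiles depend on these shares, so the SDs partly measure the difference in list length. In the lowest score decile of replicate 3, 22.2% (19.8 to 24.8%) of peaks were found in at least 1 other list, compared with 99.2% (98.4 to 99.6%) in the highest decile. The highest decile reached 99.8% in replicate 1 and 99.5% in replicate 2. Across shared peaks, which are not independent replicates, the scores correlated with a Spearman rho of 0.73 between replicates 1 and 2, 0.71 between replicates 1 and 3, and 0.75 between replicates 2 and 3.

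**Figure D2:**
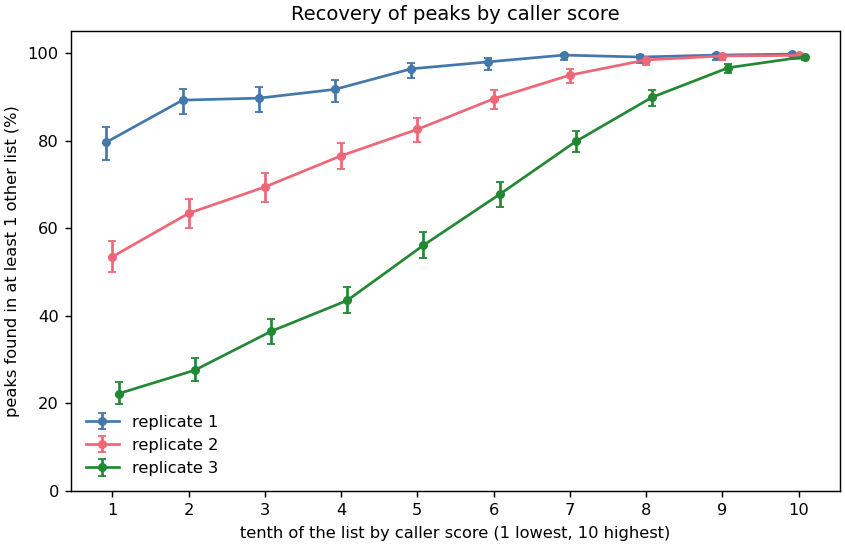
Percent of peaks found in at least 1 other replicate list (y axis) by decile of the caller score within each list (x axis, 1 lowest), with 95% Wilson intervals. Recovery is 79.6%, 53.5% and 22.2% in the lowest decile of replicates 1, 2 and 3 and above 99% in the highest decile of each.

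The strongest reproducible site lay on chromosome 10 at 13703473 to 13704027, with scores of 1354.3, 1796.3 and 1880.0 in replicates 1, 2 and 3. It was the top peak of replicates 2 and 3. The next was on chromosome 15 at 44498334 to 44498860, scoring 1215.4, 1580.5 and 1842.6. It was followed by a site on chromosome 17 at 46513754 to 46514260, a site on chromosome 5 at 150192004 to 150192509 and a second site on chromosome 15 at 55637861 to 55638394. Next by mean rank were chromosome 8 at 96887222 to 96887807, chromosome 3 at 14787275 to 14788026, chromosome 1 at 20964548 to 20965135, chromosome 2 at 60900145 to 60900794 and chromosome 15 at 7812884 to 7813410. The remaining named sites were chromosome 2 at 14234045 to 14234548, chromosome 15 at 10679345 to 10679894, chromosome 8 at 15072808 to 15073337, chromosome 2 at 104127009 to 104127508 and chromosome 9 at 61493596 to 61494246. The 15 sites were 500 to 752 bp wide after joining and had a mean score percentile of at least 99.66. Chromosome 15 held 4 of them, chromosome 2 held 3 and chromosome 8 held 2. Their scores ranged from 781.0 to 1354.3 in replicate 1, from 1160.8 to 1796.3 in replicate 2 and from 1128.8 to 1880.0 in replicate 3. The genes at these sites were not analysed here.

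Chromosome 10 carried the highest peak density and chromosome X the lowest. Relative to the whole list, peaks per Mb on chromosome 10 were 1.72 ± 0.09 (SD, n = 3), with values of 1.82, 1.67 and 1.67 in replicates 1, 2 and 3. On chromosome X the relative density was 0.20 ± 0.03, with 52, 92 and 159 peaks over a span of 160.3 Mb. Chromosome 15 stood at 1.42 ± 0.04 and chromosome 11 at 1.41 ± 0.08. Among regions with at least 2 replicates, chromosome 10 had 587, or 4.63 per Mb, chromosome X had 86, or 0.54 per Mb, and the genome as a whole had 2.70 per Mb. In the permutation of 5 Mb bins, 3 chromosomes lay above the genome mean and 1 below after adjustment: chromosome 10 (p = 1e-05, adjusted p = 0.0001), chromosome 11 (adjusted p = 0.020), chromosome 15 (adjusted p = 0.023) and chromosome X (adjusted p = 0.0001). Bins were drawn singly from the whole genome, and neighbouring bins may not be independent, so these p-values may be too small. On chromosome 10, 22 of 25 bins exceeded the genome median of 2.4 regions per Mb, and on chromosome X 0 of 32 did. The strongest site of chromosome X, at 147390102 to 147390554, had a mean score percentile of 94.97, and the strongest site of chromosome 11, at 76123415 to 76123874, one of 99.4. In the same permutation test, the call for chromosome 11 was lost without replicate 2 (adjusted p = 0.083), without replicate 3 (adjusted p = 0.093) and when only regions with all 3 replicates were counted (adjusted p = 0.086).

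**Figure D3:**
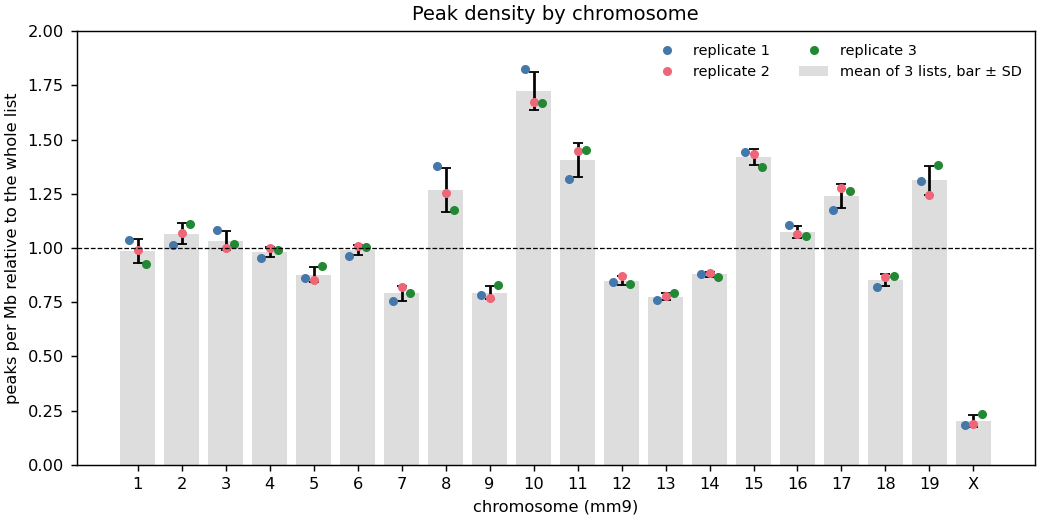
Peaks per Mb of each mm9 chromosome relative to the whole list (y axis), for replicates 1, 2 and 3 (points) with their mean and SD (bars). Chromosome 10 has a mean of 1.72 and chromosome X of 0.20; the dashed line marks a relative density of 1.

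Sites also lay closer together along the chromosomes than under uniform placement. Of the 6865 regions with at least 2 replicates, 20.7% had another within 10 kb. The 1000 uniform placements gave a mean of 5.96% and a maximum of 7.06% (one-sided permutation p = 0.001). These placements did not leave out assembly gaps or unmappable sequence. Part of the difference may thus reflect where a peak can be called at all. The median distance between neighbours was 114.7 kb, compared with 238.9 kb under uniform placement. The share depended on how many regions were counted: it was 13.2% without replicate 2 and 12.9% without replicate 3, with uniform means of 3.58% and 3.35%, and 12.7% for regions with all 3 replicates (uniform mean 3.23%). The median distance rose to 216.0 kb without replicate 2 and 228.6 kb without replicate 3. The densest 100 kb window was on chromosome 8, from 19920358 to 20020607, with 25 regions, of which 17 had all 3 replicates. The fullest 100 kb window in any uniform placement held 7. Windows with 10 or more regions formed 3 stretches: chromosome 8 at 19884058 to 20020607 with 26 regions, chromosome 8 at 19722508 to 19784907 with 20, and chromosome 1 at 85247114 to 85342285 with 12. The first of these contained the highest-scoring peak of replicate 1, at 1850.5, and peaks of up to 1724.9 in replicate 2 and 1390.9 in replicate 3. Outside these 3 stretches the fullest window held 9 regions, and the share of regions within 10 kb of another was 20.1%.

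**Figure D4:**
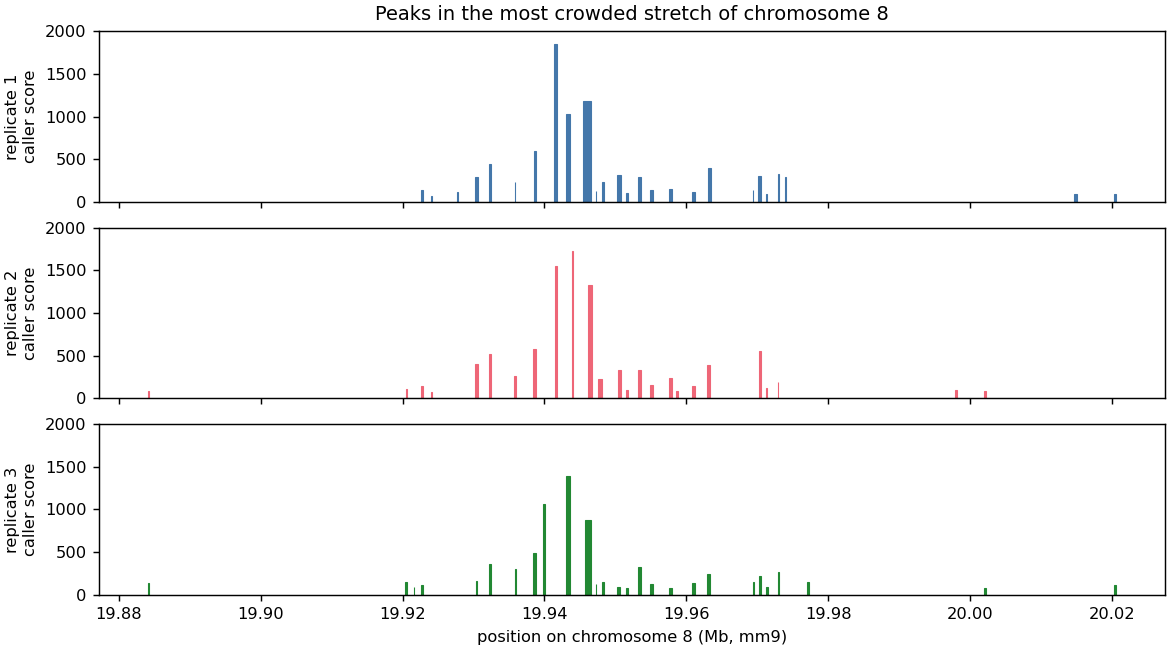
Peaks of replicates 1, 2 and 3 (panels, top to bottom) in the most crowded stretch of chromosome 8, drawn at their mm9 position (x axis, Mb) with their caller score (y axis). The highest peaks reach 1850.5, 1724.9 and 1390.9.

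The last comparison asked how the authors' merged list relates to the replicate lists. Its 13888 intervals on chromosomes 1 to 19 and X were identical, start and end, to the segments of the genome covered by peaks of at least 2 replicates, cut at every peak boundary, and all 13888 such segments were in it. Peaks of all 3 replicates covered 3583 of these segments and peaks of exactly 2 covered 10305 (74.2%). Many of its intervals are fragments of peaks: 4932 intervals (35.5%) were shorter than 50 bp and 247 were 1 bp long. Others equalled whole peaks, with 1132 identical to a peak of replicate 1, 1219 of replicate 2 and 368 of replicate 3. Joining abutting intervals left 6877 regions, or 2.02 intervals per region. The joined regions had a median width of 300 bp, compared with 400 bp for regions with at least 2 replicates built from whole peaks. A further 3 intervals lay on the mitochondrial chromosome.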

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

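In this part, the test of strong sites found in a single list and the comparison of peak numbers between replicates 1 and 3 in the dense windows were chosen after their results, or the values behind them, were seen; the other tests were written before their results, but for patterns already noticed in the data. The merged list held 3 intervals on the mitochondrial chromosome, from 5807 to 5813, 5814 to 6403 and 6404 to 6413, spanning 607 bp in all, whereas the replicate lists used here held no peak on that chromosome. They are listed because they lie in data outside the main comparisons, with no control library to set them against. In each of the 3 replicate lists, which number their peaks in alphabetical order of chromosome, exactly 1 peak number was missing between chromosome 9 and chromosome X, the place where a mitochondrial peak would stand. No replicate score for these intervals was analysed.

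The lists differed in length by up to 2.42 times. Against strong sites used in a single culture, 0.83% of the highest score decile of replicate 3 lay in no other list. A lower sensitivity in the shorter lists remains open. The recovery of replicate 3 peaks in replicate 1 was 96.9% in the highest decile and 5.73% in the lowest. With scores correlated between lists, a shorter list recovers less of the lowest decile by its length alone, so these values do not decide. Whether a lower sensitivity would come from sequencing depth, immunoprecipitation efficiency or the amount of induced HA-NUR77 was not tested. The design has no group that would give a biological explanation.

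The dense windows on chromosomes 8 and 1 held up to 25 regions in 100 kb, whereas the fullest of 1000 uniform placements held 7. This does not exclude a chance run of peaks: the fullest window outside these stretches, with 9 regions, also passed 7, so the bound set beforehand does not separate the stretches from the clustering seen across the genome. A background with that clustering was not run. The windows were picked on regions with at least 2 replicates, so only peaks of such regions were compared: there were 52, 51 and 49 in replicates 1, 2 and 3, a ratio of replicate 3 to replicate 1 of 0.94, compared with 1.60 for such peaks elsewhere (two-sided Fisher's exact test, p = 0.0099). Signal that follows a fixed background, and not the enrichment of each library, may give such a ratio. The peaks fall in only 3 stretches and are not independent, so this p is too small. A larger share of regions with all 3 replicates also moves the ratio towards 1. Over the whole lists, such regions held 3591 peaks of replicate 1 and 3592 of replicate 3. The comparison was not matched on score or on the number of supporting replicates. For reads piling up on repeated sequence, the prediction written beforehand was peaks narrow for their score. Whether such reads can also give wide peaks was not tested, so width alone cannot decide. The median width percentile among peaks of like score was 41.0, with list medians from 40.2 to 49.5. This neither meets the prediction nor excludes the explanation. The quartiles were 3 and 94 in replicate 1, 6 and 92.5 in replicate 2, and 9.5 and 80.5 in replicate 3. Both very narrow and very wide peaks for their score thus lay there, which the medians do not show. A true cluster of binding sites was not tested, because no input library or mm9 sequence was used.

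Chromosome density differed between chromosome 10 and chromosome X. A few crowded stretches on chromosome 10 are argued against, since its relative density was 1.76 after the 5 fullest bins of every chromosome were removed. Chromosome dosage that moves scores across the caller's threshold remains open. On chromosome X the median score percentile was 41.6, below the lower end of 46.9 for permuted bins. Each of the 3 lists lay below its own range. Those ranges were drawn by number of bins, not of peaks. Chromosome X held only 52, 92 and 159 peaks in replicates 1, 2 and 3, so the ranges may be too narrow for that chromosome. On chromosome 10 the median score percentile was 53.8 against an upper end of 53.4. Only replicate 2, at 55.7, lay above its own range (upper end 54.8). Replicates 1 and 3 stood at 53.3 and 53.2, so the scores decide nothing on chromosome 10. More or stronger sites on chromosome 10 could give the same values, as could fewer or weaker sites on chromosome X. Densities were not adjusted for gene density or unmappable sequence, and the copy number of this line was not analysed here.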

How the results depend on the processing

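Of 107 alternative values, 88 kept their direction and side of the threshold, stayed within the spread between lists or, for counts, stayed within 1.5 times the main count, and 0 reversed. Such a count can hide a lost call: chromosomes above the genome mean fell from 3 to 2, losing chromosome 11, without replicate 2, without replicate 3 and in regions with all 3 replicates. The 6 pairwise shares stayed above the random background (one-sided permutation p = 0.001) in all alternatives run, including a reciprocal overlap of 50%, midpoints within 100 bp, uniform placement and removal of the dense windows. They were judged only against that low background, so a share counted as kept even where it moved. With equal numbers of best peaks, the share of replicate 3 peaks in replicate 1 rose from 37.3% to 68.6%. The share of replicate 1 peaks in replicate 2 fell from 84.1% to 69.2%. Uniform placement changed only the background, not the observed shares. Keeping only peaks above the median score of their list left 3502 regions with at least 2 replicates and 1901 with all 3, and equal numbers of best peaks left 4097 with at least 2; fewer peaks entered by construction. Leaving out 1 replicate gave 3757 to 6243 regions shared by the remaining lists: 6243 without replicate 1, 4039 without replicate 2 and 3757 without replicate 3. The share of regions within 10 kb of another ranged from 12.9% to 20.2% without 1 replicate and stayed above uniform placement (one-sided permutation p = 0.001). Peak width in place of score lowered the mean Spearman rho from 0.73 to 0.58; the cause was not tested. Because the merged list holds fragments, the share of its intervals matching a peak depended on the rule. At 1 bp it was 53.2%, 81.1% and 91.4% for replicates 1, 2 and 3, under 50% reciprocal overlap 29.8%, 44.7% and 44.4%, and at identical bounds 8.15%, 8.78% and 2.65%. For regions with at least 2 replicates the shares were 99.98%, 42.5% and 0.22%, and for regions with all 3 they were 76.4%, 21.8% and 0%. With peaks above the median score only, relative density moved to 1.85 on chromosome 10, 0.16 on chromosome X and 1.54 on chromosome 15; this alternative, the removal of dense windows and the chromosome test on regions with all 3 replicates were chosen after seeing the data. Leaving out unplaced sequences, chromosome Y and the mitochondrial chromosome removed no replicate peak, and merging within a list joined none, so these 14 values say nothing about stability and are not counted above. No paired analysis was possible because there is only 1 group. The alternatives for gene position, gene lists and motifs were not run, for want of an mm9 annotation and sequence here. Read depth is unknown, so peaks absent from a list may lie under its score threshold of about 70.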

Other observations

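Outside the dense windows, the 5 Mb bins with the most regions in at least 2 replicates were on chromosome 10 from 93064527 to 98064526, with 48 regions, and from 78064527 to 83064526, with 46. Chromosome 15 from 73383361 to 78383360 followed with 41, and chromosome 10 from 13064527 to 18064526 and from 38064527 to 43064526 with 40 each. The bin on chromosome 10 that starts at 13064527 also held the strongest site of the data. The longest stretch without a peak in any of the replicate lists was 15.5 Mb on chromosome X, from 74979805 to 90496754. On the autosomes the longest was 9.52 Mb on chromosome 6, from 73173391 to 82697088. The longest on chromosome 14 was 8.19 Mb, from 109267382 to 117454281. Assembly gaps and unmappable sequence in these stretches were not analysed here. On chromosome X, 36 regions had all 3 replicates. The second strongest of these was at 19479402 to 19479854 and the third at 159291002 to 159291404.

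Strong peaks seen in a single replicate were few. In the highest score decile there were 1 in replicate 1, 4 in replicate 2 and 9 in replicate 3. The top 2 of them by within-list score percentile, at 99.987 in replicate 2 and 99.473 in replicate 3, lay at 19943888 to 19944087 and 19939758 to 19940057 on chromosome 8, inside the dense window. A pair on chromosome 1, at 87488764 to 87488963 in replicate 1 with a score of 514.8 and at 87489536 to 87489885 in replicate 3 with 538.3, lay next to each other without overlapping. These peaks were chosen after their values were seen.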
